A study of Homo sapiens with 12 samples.

How the data were processed

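The study measured poly(A) RNA of LNCaP cells, grown for 72 h under 4 conditions with 3 libraries each. Libraries were strand-specific and sequenced as 50-bp single reads. The deposited table holds TPM values that the authors computed for 60623 genes, and the submitters' processing notes name STAR, RSEM and Partek, without versions, and the builds hg38 and GRCh38. TPM divides a transcript's reads by its length and scales each library to a fixed sum, so the values are relative: a rise in an abundant class of transcripts lowers all others. The 12 libraries summed to between 999999.42 and 1000000.5, with values given to 2 decimals. Read depth is not recoverable from them, so no counting intervals or detection limits are given, and the spread between 3 libraries sets the precision.

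Genes with a mean of at least 1 TPM over all 12 libraries were tested, which left 15015, of them 12049 protein coding and 1838 lncRNA genes. Values were transformed as log2(TPM + 1), so the fold changes of weakly expressed genes are understated. A linear model with the 4 groups and no other term was fitted with limma 3.58.1 in R 4.3.3, with a trend of the variance on abundance (limma-trend), two-sided tests and Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. The contrasts read from it were each treated group against control, each pair of treated groups, and the interaction, that is, the effect of enzalutamide without DHT minus its effect with DHT. A gene is said to rise or fall only where it passed. Replicate numbers were not used as a block, because nothing says that a number marks libraries handled together.

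There were 38 gene lists with 857 members, all present in the table and 746 of them tested. They were fixed before the data were examined, with the comparisons, tests and alternatives. Each list with at least 5 tested members was compared with all other genes by camera, with a preset correlation between genes of 0.01, and again with an estimated correlation; fry tested whether a list's genes moved on balance the same way. Calls within a list are given over all genes tested and adjusted over the list alone. Named genes came from a rule of the same date: the 8 largest increases and 8 largest decreases per comparison with control, or 5 and 5 for the other contrasts, among called genes with a mean of at least 5 TPM in the higher group, no overlap between the libraries of both groups (not asked of the interaction) and a proper gene symbol; genes chosen beforehand; and up to 4 called members per list with the smallest p. Genes outside the rule are named as such.

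The androgen score of a library is the mean of log2(TPM + 1) over the tested androgen-activated genes, relative to the control mean, compared by exact two-sided permutation. The likeness of responses was measured as correlation and covariance across genes, beside 100 simulations of unchanged groups that shared the controls. Alternatives covered the pseudocount, the filter, median-of-ratios, upper-quartile and quantile scaling, leaving out the 20 most abundant and the mitochondrial genes, fits of only the groups compared, a replicate block, each library left out in turn and, chosen later, the mitochondrial share as a covariate, joint removal of the libraries with the largest shares, median-of-ratios scaling without castration + enzalutamide replicate 1, and removal of a smooth GC trend from each library. Coordinates, transcript lengths and GC content came from GENCODE release 29 on GRCh38, which located 262 of 263 named genes and gave a length for 99.2% of tested genes (14903). Tests were checked on simulated data built from these libraries, with changes of 1.25-fold, 1.5-fold, 2-fold and 4-fold. For castration versus control, 14%, 52%, 86% and 100% of the changed genes were recovered, with 8.7% false calls. For the interaction the shares were 4%, 32%, 56% and 92%, with 2.13% false calls. The fitted changes of the genes changed 1.25-fold had a median log2 size of 0.28 for castration versus control and 0.33 for the interaction. Only more abundant genes were changed and noise was independent between genes, so these shares do not describe weakly expressed genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared tables and figures. No library was left out of the main analysis. List members below the filter, NR3C1 among them, were not tested.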

Results

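Messenger RNA was sequenced from LNCaP, an established human prostate cancer line whose growth depends on androgen, after 72 h in medium with 10% charcoal-stripped serum, which holds little steroid. The 12 libraries fell into 4 groups of 3. Control medium held 0.5 nM dihydrotestosterone (DHT), the strongest natural ligand of the androgen receptor. The castration group had no DHT, the enzalutamide group had DHT and 10 µM enzalutamide (a drug that blocks the androgen receptor), and the combined group had 10 µM enzalutamide and no DHT. Abundance was given as TPM, a share of transcripts corrected for their length, and each library summed to 1000000 TPM, so the number of reads behind a value is unknown. Between 23287 and 25225 genes were above 0 TPM per library. Mitochondrial transcripts took 24.1% of the TPM in castration + enzalutamide replicate 1, 17.1% in control replicate 3 and 13.1% to 16.7% in the other 10 libraries. Pearson correlations between libraries of a group, across genes on the log2 scale, were at least 0.978 in the control, castration and enzalutamide groups and at least 0.966 in the combined group. No label says that replicates are separate cultures, so each p-value measures the spread between these samples, which is partly or wholly technical if they are not.

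**Figure D1:**
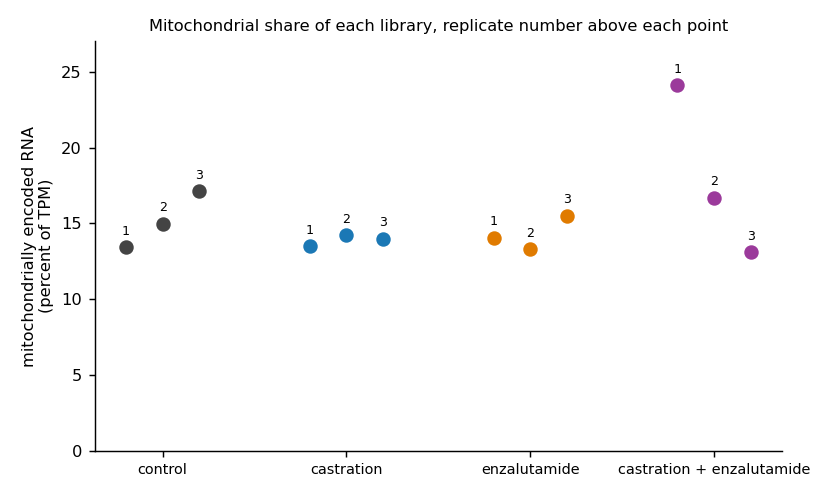
Share of TPM from mitochondrial transcripts (y axis, percent of TPM) in each of the 12 libraries (points) by group (x axis). Castration + enzalutamide replicate 1 lies at 24.1%, against 13.1% to 17.1% in the other 11 libraries.

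The comparison of castration with control asked what removal of DHT did to the transcriptome. The kallikrein genes KLK3 and KLK2, of the androgen receptor's own programme, fell most. KLK3, which encodes prostate-specific antigen (chromosome 19, 50854915 to 50860764 on GRCh38), went from 599 ± 12.1 TPM (mean ± SD, n = 3) in control to 11.3 ± 0.412 TPM, a log2 fold change of -5.61 ± 0.11 (SE). Its neighbours KLK2 (chromosome 19, 50861568 to 50880567) and KLK4 (chromosome 19, 50906352 to 50910738) fell with it, from 123 ± 2.81 to 1.62 ± 0.718 TPM and from 315 ± 14.3 to 32.2 ± 1.74 TPM. Adjusted p-values from limma were 1.05e-10 for KLK3, 1.52e-08 for KLK2 and 2.08e-10 for KLK4. KLK2 and KLK3 are similar in sequence, so reads of 50 bp can be shared between them.

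In the list of androgen-activated genes, 19 of 29 fell and 1 rose (21 and 1 adjusted over the list alone), with a median log2 fold change of -0.87 (camera adjusted p = 5.42e-12, and adjusted p = 0.212 with an estimated correlation). The prostate transporter gene SLC45A3 fell (-1.81, a log2 fold change, as are all bracketed values after gene names), as did the serine protease gene TMPRSS2 (-1.27), the receptor cochaperone FKBP5 (-1.42) and the homeobox gene NKX3-1 (-0.87). NDRG1, which was picked out after its values were seen, was the member that rose (0.67). Of the androgen-repressed genes, 6 of 8 rose and 2 fell (the same numbers as when adjusted over the list alone), with a median of 1.29 (camera adjusted p = 0.0297, and adjusted p = 0.709 with an estimated correlation). The androgen receptor gene AR (chromosome X, 67544032 to 67730619) rose from 52 ± 10.5 to 115.7 ± 6.78 TPM (1.16 ± 0.17, adjusted p = 2.12e-04). Also higher were the opioid receptor gene OPRK1 (3.21), the chemokine receptor gene ACKR3 (1.71) and the steroid-glucuronidating enzymes UGT2B15 (1.44) and UGT2B17 (1.42). Those last enzymes are near-identical copies, so their separate values are uncertain. UGT2B11 and UGT2B28, of the same enzyme family, fell by 1.44 and 1.94 and were likewise picked out after their values were seen.

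Genes of DNA replication and mitosis fell as a body after castration. All 35 tested genes of the G2/M and mitosis list fell, whether adjusted over all genes or adjusted over the list alone, with a median log2 fold change of -1.76 (camera adjusted p = 1.63e-27, and adjusted p = 0.121 with an estimated correlation). The ubiquitin-conjugating enzyme gene UBE2C fell (-2.11), as did the kinetochore gene CENPF (-1.99), the cyclin gene CCNB1 (-1.76) and DNA topoisomerase TOP2A (-1.74). TOP2A went from 55.5 ± 5.93 to 16.1 ± 3.61 TPM. MKI67, a marker of cycling cells, fell (-1.52). For G1/S and DNA replication, 39 of 40 fell and 0 rose (the same numbers as when adjusted over the list alone), with a median of -1.41 (camera adjusted p = 3.10e-24, and adjusted p = 0.142 with an estimated correlation). The transcription factor E2F1 fell (-1.85), as did thymidine kinase TK1 (-1.85) and the replication clamp PCNA (-1.59). CCND1, the cyclin D1 gene, was the member not called (0.30 ± 0.14). For homologous recombination and Fanconi repair, 21 of 24 fell and 0 rose (22 and 0 adjusted over the list alone), with a median of -1.21 (camera adjusted p = 5.41e-14, and adjusted p = 0.121 with an estimated correlation), and RAD51AP1 and FANCA fell (-1.94 and -1.68). Among cyclin-dependent kinase inhibitors and quiescence genes, 6 of 12 rose and 3 fell (6 and 4 adjusted over the list alone); CDKN1C and CDKN2B rose by 0.89 and 0.81 and CDKN2C fell (-0.84). CDKN1A rose by 0.58, but lost its call without control replicate 2, control replicate 3 or castration replicate 3, while CDKN1B was at 0.18 ± 0.21, not called.

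MYC and most of its listed targets in ribosome biogenesis fell. MYC (chromosome 8, 127735434 to 127741434), a transcription factor that promotes growth, fell from 334 ± 37.2 to 133 ± 18.9 TPM (-1.33 ± 0.14, adjusted p = 2.56e-05). Of the MYC targets in ribosome biogenesis, 26 of 32 fell and 1 rose (27 and 1 adjusted over the list alone), with a median of -0.78 (camera adjusted p = 4.39e-15, and adjusted p = 0.121 with an estimated correlation). The nucleolar protein genes NOP56, NOP16 and LYAR fell (-1.14, -1.44 and -1.44). The cytosolic ribosomal proteins moved less, with 1 up and 26 down of 74 (0 and 25 adjusted over the list alone) and a median of -0.07 (camera adjusted p = 4.12e-06, and adjusted p = 0.554 with an estimated correlation). In the ATF4 and amino acid response list, 16 of 22 fell and 0 rose (18 and 0 adjusted over the list alone), with a median of -0.67 (camera adjusted p = 6.96e-10, and adjusted p = 0.121 with an estimated correlation). ATF4 itself, the transcription factor of that response, fell (-0.69), as did glycyl-tRNA synthetase GARS1 (-1.12) and CHAC1 (-1.53). The glutamine transporter SLC1A5 fell (-1.75), within a glutamine and aspartate list that had 1 up and 5 down of 13 (1 and 5 adjusted over the list alone). Polyamine genes went both ways, with 4 up and 4 down of 12 (5 and 4 adjusted over the list alone); spermidine synthase SRM fell (-1.26). The mitochondrial chaperonins HSPD1 and HSPE1 fell (-0.79 and -0.83), and the heat shock list had 0 up and 3 down of 11 (0 and 3 adjusted over the list alone).

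Energy and lipid metabolism changed in several directions after castration. HK2, the hexokinase at the entry to glycolysis (chromosome 2, 74833981 to 74893359), fell from 10.2 ± 1.4 to 3.5 ± 0.425 TPM (-1.31 ± 0.16, adjusted p = 7.43e-05). In the glycolysis list, 10 of 23 fell and 4 rose (11 and 4 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.0221, and adjusted p = 0.738 with an estimated correlation). ENO1 and LDHB fell (-0.82 and -0.78), whereas ENO2 and ALDOC rose by 1.38 and 0.67. Nuclear-encoded respiratory chain genes had 4 up and 30 down of 73 (4 and 32 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 3.83e-05, and adjusted p = 0.524 with an estimated correlation). The ATP synthase gene ATP5MC1 fell (-0.90), as did the complex I gene NDUFB10 (-0.82), while NDUFB4 and NDUFA4 rose by 0.47 and 0.45. The regulators of mitochondrial biogenesis had 1 up and 6 down of 12 (1 and 8 adjusted over the list alone) (camera adjusted p = 0.00300, and adjusted p = 0.121 with an estimated correlation); the mitochondrial helicase TWNK fell (-1.02), as did PPRC1 (-0.87). DNM1L, which divides mitochondria, was at -0.19 ± 0.15 (adjusted p = 0.342), not called. The fission and fusion list had 1 up and 2 down of 14 (0 and 1 adjusted over the list alone), and its member MTFP1 fell (-1.82). None of the 13 mitochondrially encoded mRNAs was called by limma, over all genes or adjusted over the list alone, at a list median of -0.23.

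More genes of lipid synthesis fell than rose, and more genes of fatty acid oxidation rose than fell. For fatty acid synthesis and desaturation, 8 of 15 fell and 1 rose (10 and 1 adjusted over the list alone) (camera adjusted p = 2.67e-04, and adjusted p = 0.554 with an estimated correlation), led by the elongases ELOVL7 and ELOVL5, which fell (-1.82 and -1.66), and by fatty acid synthase FASN, which fell (-1.02). For cholesterol synthesis and uptake, 14 of 24 fell and 2 rose (14 and 3 adjusted over the list alone) (camera adjusted p = 4.84e-05, and adjusted p = 0.554 with an estimated correlation). DHCR24, EBP and FDPS fell (-1.28, -1.13 and -0.88), and TM7SF2 rose by 0.95. For fatty acid oxidation, 12 of 21 rose and 3 fell (13 and 3 adjusted over the list alone) (camera adjusted p = 0.0297, and adjusted p = 0.642 with an estimated correlation), with CPT1C and ETFB up by 1.51 and 0.97. For autophagy and lysosome, 16 of 24 rose and 2 fell (18 and 2 adjusted over the list alone) (camera adjusted p = 0.00125, and adjusted p = 0.642 with an estimated correlation); the autophagy kinase ULK1 rose by 0.73 and cathepsin B (CTSB) by 0.72. Immediate early genes, the first transcribed after a stimulus, had 7 up and 0 down of 12 (7 and 0 adjusted over the list alone) (camera adjusted p = 0.0297, and adjusted p = 0.226 with an estimated correlation). EGR1 rose by 2.21, FOSL2 by 1.59 and JUNB by 0.83.

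Outside the lists, the gene that rose most in castration was AOC1, a diamine oxidase (chromosome 7, 150824627 to 150861504), from 0.43 ± 0.195 to 21 ± 3.3 TPM (3.95 ± 0.13). The secreted phospholipase PLA2G2A (chromosome 1, 19975431 to 19980416) rose from 13.4 ± 2.96 to 192 ± 32.3 TPM (3.75 ± 0.15). IFI27L2 rose by 3.58, PCDH11X by 3.10 and the F-box gene FBXO2 by 2.61. PCDH11X has a near-identical copy, PCDH11Y, so its own value is uncertain. PCDH11Y was the more abundant, at 4.33 ± 0.701 TPM in control and 69.8 ± 5.04 TPM in castration. PCDH11X was at 0.147 ± 0.047 and 8.84 ± 1.09 TPM. AMIGO3 reached 8.3 ± 0.771 TPM and was listed at 0 in all 3 controls. Besides the kallikreins, the membrane protein gene TM4SF1 fell (-3.10), as did ADAM7 (-3.00). MIR4763 and SNORD88C were also among the 8 that fell most (-3.23 and -3.07), but these are very short genes within or beside other genes, and their TPM is uncertain.

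The remaining lists held fewer or mixed changes, and camera called none of them in castration. The TCA cycle list had 6 up and 7 down of 28 (6 and 7 adjusted over the list alone), with PDHA1 down (-0.48) and IDH3G up by 0.52. p53 targets had 3 up and 6 down of 20 (3 and 6 adjusted over the list alone); GDF15 fell (-0.94) and TP53I3 rose by 1.37. Endoplasmic reticulum chaperones had 7 up and 4 down of 22 (7 and 4 adjusted over the list alone), including HSPA5 at 0.65. Hypoxia-induced genes had 6 up and 1 down of 13 (6 and 1 adjusted over the list alone), with ADM up by 1.05 and HILPDA down (-0.88). Interferon-stimulated genes had 6 up and 2 down of 18 (6 and 3 adjusted over the list alone); BST2 rose by 1.13 and OAS3 fell (-1.31). MHC class I presentation genes had 6 up and 3 down of 12 (6 and 3 adjusted over the list alone), with TAPBP up by 1.15 and HLA-A by 0.93, the latter uncertain because HLA genes vary between genomes. Luminal markers had 7 up and 4 down of 16 (9 and 4 adjusted over the list alone), with CD24 up by 1.54, and basal markers had 1 up and 1 down of 4 (1 and 1 adjusted over the list alone), with ITGB4 up from 1.57 ± 0.561 to 6.22 ± 1.24 TPM; only 4 basal markers were tested and camera was not run on them. Neuroendocrine markers had 1 up and 3 down of 6 (1 and 3 adjusted over the list alone); ENO2 rose by 1.38 and EZH2, which also rises in cycling cells, fell (-1.08). Mesenchymal markers had 2 up and 2 down of 6 (2 and 2 adjusted over the list alone), with VIM at 0.53. Glucocorticoid receptor targets had 4 up and 1 down of 10 (5 and 1 adjusted over the list alone); MT2A fell (-1.49), and the receptor gene NR3C1 itself was below the filter. Steroid metabolism genes had 5 up and 1 down of 11 (6 and 1 adjusted over the list alone), with AKR1C3 up by 0.99, and xenobiotic receptor targets had 2 up and 0 down of 5 (2 and 0 adjusted over the list alone), with CYP2C9 up by 0.78. Receptor tyrosine kinase and insulin genes had 5 up and 0 down of 15 (4 and 0 adjusted over the list alone), with ERBB2 up by 1.21. Replication-dependent histone genes had 5 up and 2 down of 12 (6 and 4 adjusted over the list alone), with H4C8 up by 1.11. Only poly(A) RNA was measured, so histone transcripts without a poly(A) tail are not covered by these values. Of the markers of leukocytes, fibroblasts and endothelium, 2 rose and 1 fell of 5 (2 and 1 adjusted over the list alone), ACTA2 falling (-1.45) and COL1A1 rising by 1.17. List medians turned sign under another scaling for fission and fusion (main 0.00), polyamine (main 0.06) and histone genes (main 0.10).

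**Figure D2:**
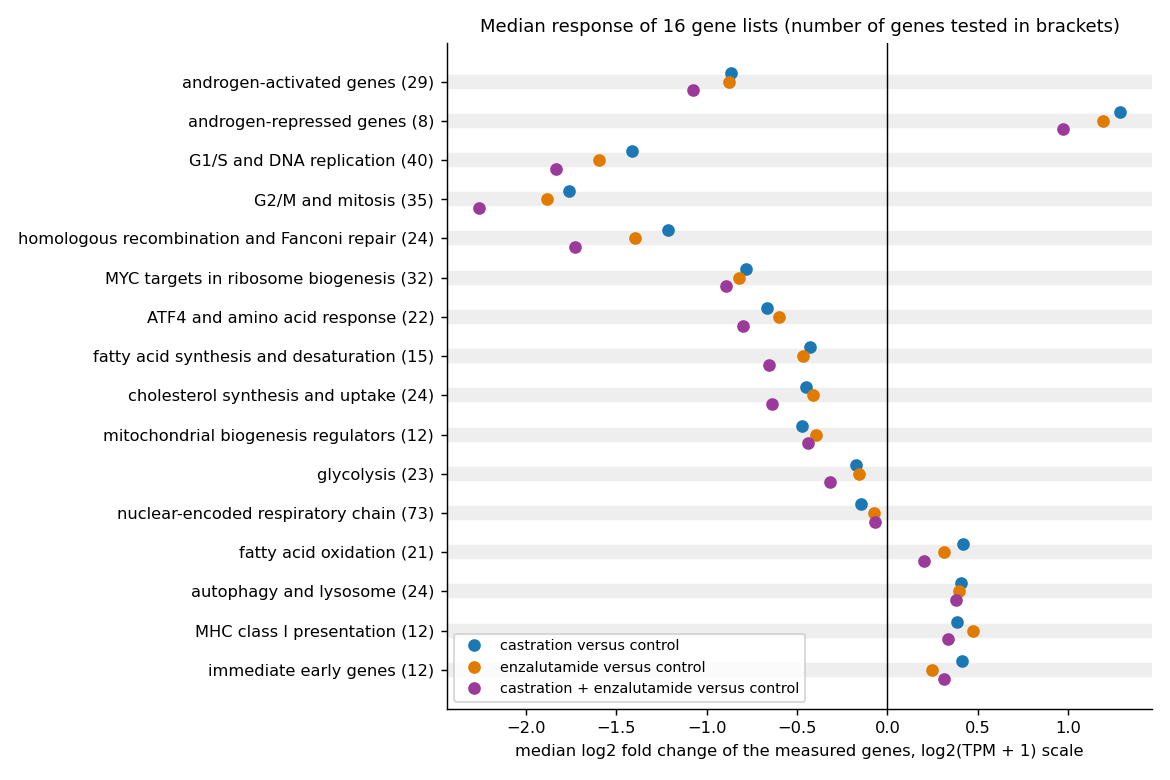
Median log2 fold change against control (x axis, log2(TPM + 1) scale) of the tested genes of 16 lists (y axis, number of genes in brackets), with a point for each treated group. The G2/M and mitosis list lies at -1.76 to -2.26 and the androgen-repressed list at 0.97 to 1.29; the points of the respiratory chain list, at -0.15 to -0.07, turned sign for the combined group under upper-quartile and quantile scaling.

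Across all 15015 genes tested, limma called 6268 in castration, 3841 up and 2427 down, of which 692 rose and 496 fell at least 2-fold. The balance of directions depended on the scaling: the median log2 fold change of all genes was 0.12 on the TPM scale and 0.00 with median-of-ratios scaling, where 48.0% of the 6654 calls were up in place of 61.3%. Removal of a GC trend gave 47.8% of 6999 calls up. Of common reference genes, GAPDH fell by 0.25 and ACTB was at -0.03, not called. None of the camera calls above passed 0.05 with an estimated correlation, while fry called 23 of 37 lists.

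**Figure D3:**
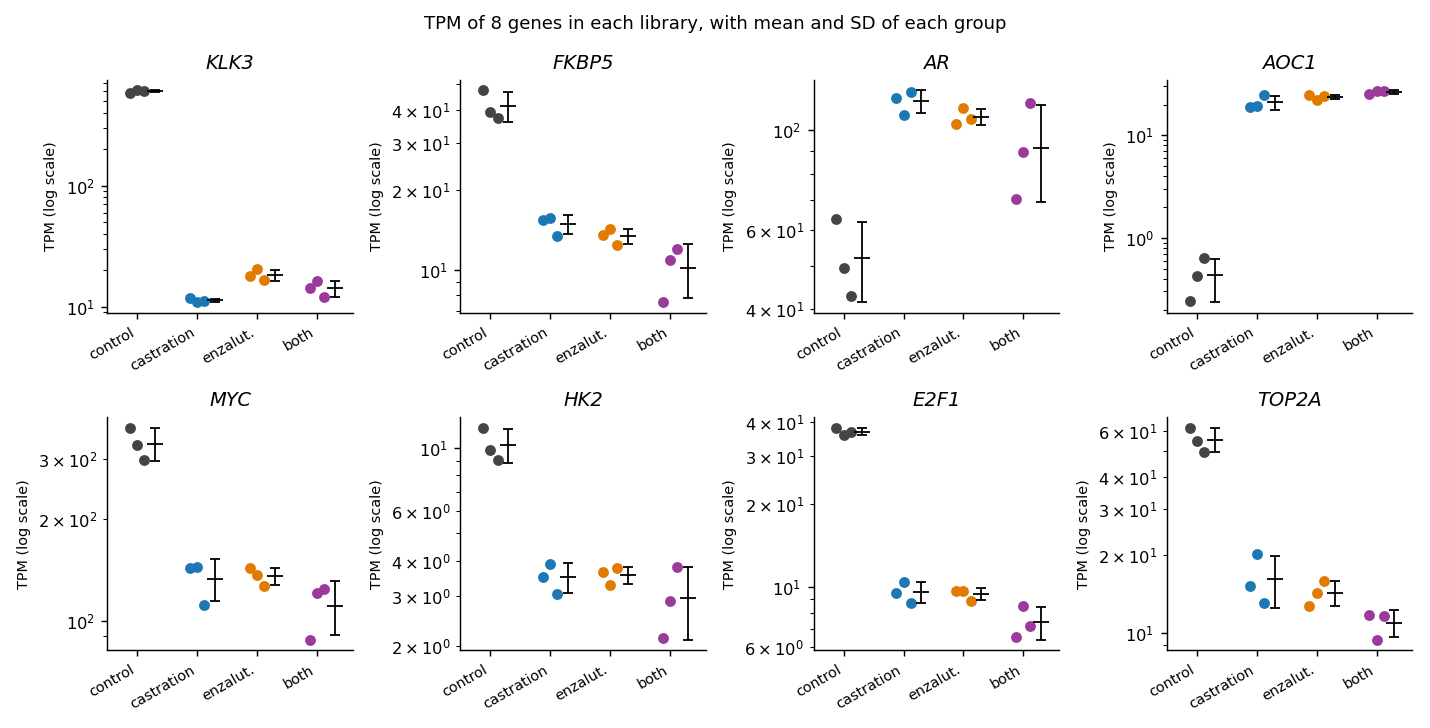
TPM (y axis, log scale) of 8 genes in each of the 12 libraries (points, 3 per group) by group (x axis), with the mean and SD of each group as a bar beside the points. KLK3 lies near 599 TPM in control and at 18.3 TPM or less on average in the treated groups, while AOC1 goes from 0.43 TPM to 21 TPM or more.

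The comparison of enzalutamide with control asked what blocking the receptor did while DHT was present. The kallikrein genes fell again: KLK3 from 599 ± 12.1 to 18.3 ± 1.92 TPM (mean ± SD, n = 3; -4.97 ± 0.11 on the log2 scale, limma adjusted p = 4.11e-10), KLK2 to 2.93 ± 0.862 TPM and KLK4 to 45.4 ± 2.3 TPM. Of androgen-activated genes, 21 of 29 fell and 0 rose (22 and 1 adjusted over the list alone), with a median of -0.88 (camera adjusted p = 8.15e-12, and adjusted p = 0.218 with an estimated correlation). TMPRSS2, FKBP5 and NKX3-1 fell (-0.95, -1.55 and -0.73). Of androgen-repressed genes, 6 of 8 rose and 2 fell (the same numbers as when adjusted over the list alone), with a median of 1.19 (camera adjusted p = 0.0257, and adjusted p = 0.669 with an estimated correlation). AR rose to 107 ± 4.34 TPM (1.04 ± 0.17, adjusted p = 4.56e-04), OPRK1 by 3.18, UGT2B15 by 1.54 and UGT2B17 by 1.34.

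Proliferation genes fell with enzalutamide too. All 35 G2/M and mitosis genes fell, also when adjusted over the list alone, with a median of -1.89 (camera adjusted p = 3.16e-28, and adjusted p = 0.121 with an estimated correlation); UBE2C fell (-2.24), as did TOP2A (-1.89) and MKI67 (-1.73). In G1/S and DNA replication, 39 of 40 fell and 0 rose (the same numbers as when adjusted over the list alone) (camera adjusted p = 2.33e-25, and adjusted p = 0.128 with an estimated correlation), E2F1 falling (-1.87); CCND1 was at 0.21, not called. In homologous recombination and Fanconi repair, 21 of 24 fell and 0 rose (22 and 0 adjusted over the list alone) (camera adjusted p = 3.60e-14, and adjusted p = 0.121 with an estimated correlation), FANCA falling (-1.83). MYC fell to 135 ± 8.19 TPM (-1.29 ± 0.14, adjusted p = 3.16e-05). Of its targets in ribosome biogenesis, 26 of 32 fell and 1 rose (27 and 1 adjusted over the list alone) (camera adjusted p = 1.63e-15, and adjusted p = 0.121 with an estimated correlation), including NOP56 (-1.23) and LYAR (-1.53). In the ATF4 list, 16 of 22 fell and 0 rose (18 and 1 adjusted over the list alone) (camera adjusted p = 2.59e-09, and adjusted p = 0.128 with an estimated correlation), CHAC1 falling (-1.64) and GARS1 (-1.19). Kinase inhibitor genes had 5 up and 4 down of 12 (6 and 4 adjusted over the list alone); CDKN1A was at 0.41 and CDKN1B at 0.17, neither called.

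Metabolic genes moved with enzalutamide as follows. HK2 fell to 3.57 ± 0.246 TPM (-1.29 ± 0.16), and glycolysis genes had 2 up and 10 down of 23 (2 and 10 adjusted over the list alone) (camera adjusted p = 0.0242, and adjusted p = 0.748 with an estimated correlation), with ENO1 down (-0.83) and ENO2 up by 1.33. Respiratory chain genes had 8 up and 23 down of 73 (8 and 25 adjusted over the list alone) (camera adjusted p = 0.0146, and adjusted p = 0.671 with an estimated correlation), with ATP5MC1 down (-0.78). Mitochondrial biogenesis regulators had 0 up and 7 down of 12 (0 and 7 adjusted over the list alone) (camera adjusted p = 0.00211, and adjusted p = 0.121 with an estimated correlation), with TWNK down (-1.07). DNM1L was at -0.41 ± 0.15 (adjusted p = 0.0534), not called. Fatty acid synthesis genes had 1 up and 9 down of 15 (1 and 11 adjusted over the list alone) (camera adjusted p = 2.90e-04, and adjusted p = 0.629 with an estimated correlation), cholesterol genes 3 up and 14 down of 24 (3 and 14 adjusted over the list alone) (camera adjusted p = 2.90e-04, and adjusted p = 0.629 with an estimated correlation) and fatty acid oxidation genes 10 up and 1 down of 21 (10 and 2 adjusted over the list alone) (camera adjusted p = 0.0277, and adjusted p = 0.644 with an estimated correlation). FASN and DHCR24 fell (-1.06 and -1.26), and CPT1C rose by 1.48. Autophagy and lysosome genes had 16 up and 2 down of 24 (16 and 2 adjusted over the list alone) (camera adjusted p = 7.10e-04, and adjusted p = 0.629 with an estimated correlation), with CTSB up by 0.78. Heat shock proteins had 0 up and 4 down of 11 (0 and 4 adjusted over the list alone) (camera adjusted p = 0.0242, and adjusted p = 0.644 with an estimated correlation), with HSPD1 down (-0.85). Of immediate early genes, 6 of 12 rose and 1 fell (6 and 2 adjusted over the list alone), without a camera call (adjusted p = 0.142); EGR1 rose by 2.41.

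Among single genes, AOC1 rose to 23.7 ± 1.24 TPM (4.12 ± 0.13), PLA2G2A to 167 ± 13 TPM (3.55 ± 0.15) and IFI27L2 by 3.46. TM4SF1 fell (-3.18), as did the sialyltransferase ST6GALNAC1 (-3.13) and ADAM7 (-2.99). MIR6850 was listed at 0 in all 3 enzalutamide libraries and is, like MIR6763 and SNORD36C in the same group of largest changes, too short for a firm TPM. In all, limma called 5797 genes, 3349 up and 2448 down, with 580 up and 539 down at least 2-fold. With the GC trend removed 47.6% of 6606 calls were up, against 57.8% on the TPM scale. The medians of the TCA cycle (main 0.04), polyamine (main 0.04), ribosomal protein (main 0.03), neuroendocrine (main 0.01), mesenchymal (main 0.02), glucocorticoid (main 0.06) and histone lists (main 0.04) turned sign under another scaling.

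Castration and enzalutamide together, compared with control, lowered the kallikreins to levels between those of the single treatments. KLK3 fell to 14.2 ± 2.21 TPM (mean ± SD, n = 3; -5.31 ± 0.11 on the log2 scale, limma adjusted p = 1.94e-10), KLK2 to 2.21 ± 0.46 TPM and KLK4 to 40.8 ± 1.86 TPM. In the androgen-activated list, 24 of 29 fell and 0 rose (the same numbers as when adjusted over the list alone), with a median of -1.08 (camera adjusted p = 3.31e-12, and adjusted p = 0.179 with an estimated correlation). FKBP5 fell (-1.94), as did TMPRSS2 (-1.03) and NKX3-1 (-0.89). Of androgen-repressed genes, 6 of 8 rose and 2 fell (the same numbers as when adjusted over the list alone) (camera adjusted p = 0.0181, and adjusted p = 0.639 with an estimated correlation). AR rose to 91.4 ± 22.3 TPM (0.79 ± 0.17, adjusted p = 0.00269) and OPRK1 by 2.98, whereas UGT2B11 fell (-1.71).

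All 35 G2/M and mitosis genes were lower in the combined group than in control, also when adjusted over the list alone, with a median of -2.26 (camera adjusted p = 4.04e-26, and adjusted p = 0.131 with an estimated correlation). Cyclin A2 (CCNA2) and CENPF fell (-2.49 and -2.49), as did TOP2A (-2.24), MKI67 (-2.30) and the spindle protein gene NUSAP1 (-2.92). For G1/S and DNA replication, 39 of 40 fell and 0 rose (the same numbers as when adjusted over the list alone), with a median of -1.83 (camera adjusted p = 6.32e-24, and adjusted p = 0.131 with an estimated correlation), E2F1 falling (-2.18). CCND1 was at -0.00 and not called. For homologous recombination and Fanconi repair, 22 of 24 fell and 0 rose (23 and 0 adjusted over the list alone) (camera adjusted p = 8.84e-14, and adjusted p = 0.131 with an estimated correlation), with RAD51AP1 down (-2.31). MYC fell to 111 ± 19.99 TPM (-1.59 ± 0.14, adjusted p = 5.66e-06), and of its targets in ribosome biogenesis 29 of 32 fell and 1 rose (the same numbers as when adjusted over the list alone) (camera adjusted p = 1.27e-14, and adjusted p = 0.131 with an estimated correlation). For the ATF4 list, 18 of 22 fell and 1 rose (the same numbers as when adjusted over the list alone) (camera adjusted p = 1.74e-08, and adjusted p = 0.131 with an estimated correlation); the serine enzyme PSAT1 and asparagine synthetase ASNS fell (-1.70 and -1.63).

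HK2 fell to 2.95 ± 0.841 TPM (-1.52 ± 0.16) in the combined group, and glycolysis genes had 2 up and 12 down of 23 (2 and 14 adjusted over the list alone) (camera adjusted p = 0.00842, and adjusted p = 0.71 with an estimated correlation), with LDHA down (-1.41). DNM1L fell (-0.59 ± 0.15, adjusted p = 0.00933), a call lost when only the groups compared were fitted. Against enzalutamide alone DNM1L was at -0.18, and at 0.01 without castration + enzalutamide replicate 1. Fission and fusion genes had 1 up and 5 down of 14 (1 and 5 adjusted over the list alone), with MTFP1 down (-1.63). The mean log2 value of that list relative to control was -0.68 in castration + enzalutamide replicate 1, and -0.27 and -0.10 in replicates 2 and 3. Fatty acid synthesis genes had 1 up and 12 down of 15 (1 and 13 adjusted over the list alone) (camera adjusted p = 1.87e-04, and adjusted p = 0.565 with an estimated correlation), cholesterol genes 2 up and 15 down of 24 (2 and 17 adjusted over the list alone) (camera adjusted p = 1.52e-04, and adjusted p = 0.582 with an estimated correlation), fatty acid oxidation genes 7 up and 2 down of 21 (7 and 2 adjusted over the list alone) (camera adjusted p = 0.0262, and adjusted p = 0.639 with an estimated correlation) and glutamine and aspartate genes 1 up and 7 down of 13 (1 and 8 adjusted over the list alone) (camera adjusted p = 0.0156, and adjusted p = 0.639 with an estimated correlation). ELOVL5 fell (-2.03), as did SLC25A13 (-1.10), and ETFB rose by 1.10. Mitochondrial biogenesis regulators had 0 up and 8 down of 12 (0 and 8 adjusted over the list alone) (camera adjusted p = 0.00281, and adjusted p = 0.131 with an estimated correlation) and heat shock proteins 0 up and 6 down of 11 (0 and 6 adjusted over the list alone) (camera adjusted p = 0.0136, and adjusted p = 0.639 with an estimated correlation), with HSPE1 down (-0.90) and HSP90AB1 (-0.39). Autophagy and lysosome genes had 14 up and 2 down of 24 (15 and 2 adjusted over the list alone) (camera adjusted p = 2.43e-04, and adjusted p = 0.582 with an estimated correlation), immediate early genes 5 up and 1 down of 12 (5 and 1 adjusted over the list alone) (camera adjusted p = 0.00842, and adjusted p = 0.131 with an estimated correlation) and MHC class I genes 6 up and 1 down of 12 (7 and 2 adjusted over the list alone) (camera adjusted p = 0.0149, and adjusted p = 0.383 with an estimated correlation). Respiratory chain genes had 15 up and 21 down of 73 (15 and 22 adjusted over the list alone), with no camera call and a median of -0.07 that was 0.04 with upper-quartile scaling. Among mitochondrially encoded mRNAs 1 up and 0 down of 13 (0 and 0 adjusted over the list alone) were called, the 1 being MT-ND3 (0.49); without castration + enzalutamide replicate 1, the library with the mitochondrial share of 24.1%, MT-ND3 was not called.

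AOC1 rose to 26.4 ± 1.11 TPM (4.27 ± 0.13), PLA2G2A to 198 ± 3.44 TPM (3.81 ± 0.15) and the matrix gene MATN2 by 2.63. ST6GALNAC1 fell (-3.39), as did TM4SF1 (-3.31) and the protease gene FAM111B (-3.02). In all, limma called 5883 genes, 2673 up and 3210 down, with 456 up and 663 down at least 2-fold. Calls up were 45.4% of these, but 54.6% of 6428 without castration + enzalutamide replicate 1 and 57.9% of 6585 with upper-quartile scaling. They were 38.0% of 6064 without castration + enzalutamide replicate 3. Receptor tyrosine kinase genes called up went from 1 to 7 without castration + enzalutamide replicate 1. Kinase inhibitor genes called up went from 3 to 6 and TCA cycle genes from 2 to 6 in that setting. The medians of the ribosomal protein, mitochondrially encoded, chaperone, basal and xenobiotic lists, all within 0.13 of 0, turned sign under another scaling.

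How alike were loss of DHT and blockade of its receptor? Log2 fold changes against control correlated across 15015 genes at Pearson r = 0.93 and Spearman rho = 0.93, with a slope of 0.91 for enzalutamide on castration; genes are not independent replicates. Of the calls, 3023 genes rose and 2128 fell in both, and 0 were called by limma in opposite directions. Lists drawn independently would share 857 up and 396 down. Both comparisons use the same 3 controls: 100 simulations of unchanged groups against shared controls gave a mean r of 0.506 and a covariance of 0.0292, against a measured covariance of 0.318. Those simulations shared 0.02 calls on average. The 3 controls are too few to be split with at least 2 on each side, so part of the excess over independent lists can come from them. Responses to the combination correlated with those to castration at 0.873 and to enzalutamide at 0.89. As a single score, the mean log2 value of the androgen-activated genes relative to control (SD 0.13) was -1.21 ± 0.06 in castration, -1.16 ± 0.02 in enzalutamide and -1.38 ± 0.25 in the combined group (SD, n = 3). All libraries of each of these 3 groups lay below all controls, which gives an exact two-sided permutation p = 0.1, the smallest that 3 against 3 allow (adjusted p = 0.15 over 6 comparisons).

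**Figure D4:**
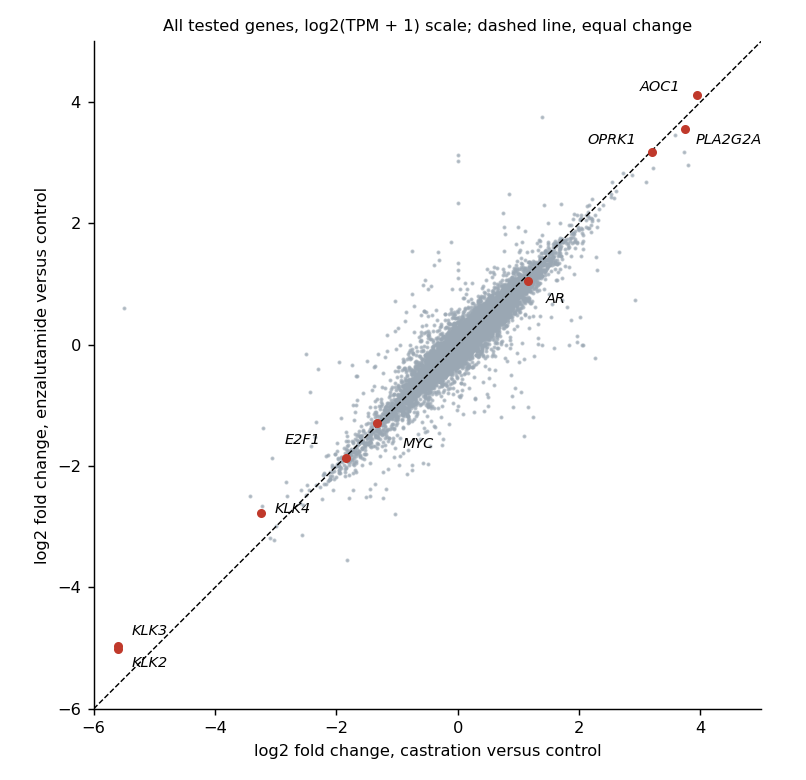
Log2 fold change against control for enzalutamide (y axis) and castration (x axis), with a point for each of the 15015 tested genes, 9 of them named, and a dashed line of equal change. The points follow the line (Pearson r = 0.93 across genes, with 3 shared control libraries), from KLK3 and KLK2 at the bottom left to AOC1 at the top right.

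Enzalutamide was compared directly with castration. The kallikreins stood slightly higher with enzalutamide: KLK3 at 18.3 ± 1.92 against 11.3 ± 0.412 TPM (0.64 ± 0.11, limma adjusted p = 0.232) and KLK4 at 45.4 ± 2.3 against 32.2 ± 1.74 TPM (0.48 ± 0.07, adjusted p = 0.098). KLK4 was picked out after its values were seen, as were the lysosomal cholesterol carrier NPC2 (0.46) and NUCB2 (0.44) at the same adjusted p. MYC differed by 0.04 ± 0.14, AR by -0.11 ± 0.17 and DNM1L by -0.22 ± 0.15, none called. Of 15015 genes, limma called 0, with 566 at an unadjusted p under 0.05; other settings called 0 to 6. AP000769.5, annotated as a miscellaneous RNA and listed at 0 in castration, had the lowest adjusted p (0.0615) and was picked out likewise. The median 95% confidence interval reached 0.32 either side, and 98.1% of genes differed by less than 0.58. Within the androgen-activated list, 0 genes were called over all genes and 2 rose when adjusted over the list alone (camera adjusted p = 0.0134, and adjusted p = 0.993 with an estimated correlation). Camera also called ribosomal proteins (median 0.10, adjusted p = 3.23e-35, and adjusted p = 0.200 with an estimated correlation) and the respiratory chain (median 0.05, adjusted p = 4.72e-10, and adjusted p = 0.411 with an estimated correlation). Over 37 lists, camera called 3 in this comparison and fry called 1. The androgen score differed by 0.05 (exact permutation p = 0.3).

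Adding enzalutamide to castration gave lower values for cell-cycle genes without a single call among them. MKI67 stood at 4.33 ± 1.51 TPM against 8.03 ± 1.9 in castration (-0.78 ± 0.22, limma adjusted p = 0.233), and TOP2A at 10.9 ± 1.3 against 16.1 ± 3.61 (-0.51 ± 0.15). All 35 G2/M and mitosis genes lay below 0, with a median of -0.50; 0 were called by limma over all genes and 25 fell when adjusted over the list alone (camera adjusted p = 2.16e-10, and adjusted p = 0.716 with an estimated correlation). The median was -0.29 with a GC trend removed. By the mean log2 value of the list relative to control, castration replicate 3 (-2.07, against -1.67 and -1.57 in replicates 1 and 2) lay close to castration + enzalutamide replicate 3 (-2.13). G1/S and DNA replication had a median of -0.44, with 0 called and 24 falling when adjusted over the list alone (camera adjusted p = 1.50e-09, and adjusted p = 0.767 with an estimated correlation). The median was -0.27 with median-of-ratios scaling and no castration + enzalutamide replicate 1. Homologous recombination genes had a median of -0.35, with 0 called and 6 falling when adjusted over the list alone (camera adjusted p = 0.00531, and adjusted p = 0.942 with an estimated correlation). KLK3 was at 0.30 ± 0.11 and DNM1L at -0.40 ± 0.15, neither called. KLK3 ranged from 0.20 to 0.49 over the alternatives. DNM1L was at -0.21 without castration + enzalutamide replicate 1 and at -0.13 with the mitochondrial share as a covariate. With a GC trend removed TOP2A was at -0.24. Camera put mitochondrially encoded mRNAs (0.40; adjusted p = 2.42e-09, and adjusted p = 0.716 with an estimated correlation) above other genes, in a group that holds the library with a mitochondrial share of 24.1%; without it the median was 0.12. Without castration + enzalutamide replicate 3 it was 0.63, and with a GC trend removed 0.60. The respiratory chain (camera adjusted p = 2.41e-17, and adjusted p = 0.224 with an estimated correlation), ribosomal proteins (camera adjusted p = 9.49e-26, and adjusted p = 0.224 with an estimated correlation) and MHC class I genes (camera adjusted p = 0.00399, and adjusted p = 0.577 with an estimated correlation) lay above other genes too. Androgen-repressed genes lay below them (camera adjusted p = 0.0316, and adjusted p = 0.942 with an estimated correlation). Over 37 lists, camera called 8 in this comparison and fry called 1.

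Of 15015 genes, limma called 1, with 3094 at an unadjusted p under 0.05; other settings that used all libraries called 0 to 5. That gene, AL049650.2, named after its values were seen, was listed at 0 in all 3 combined libraries and at 2.64 to 3.66 TPM in castration (adjusted p = 7.82e-04). Controls had 0.05 TPM or less of it, so its level with both treatments was near that of control. With castration + enzalutamide replicate 3 left out the count of called genes was 2284, 133 up and 2151 down, so it depends on that library. Left in the combined group were replicates 1 and 2, with mitochondrial shares of 24.1% and 16.7%. Their median log2 values lay 0.32 and 0.06 below the mean of the library medians. No rescaled fit was made without replicate 3, so a shift of all values cannot be told apart from a difference in single genes. The androgen score was lower by an amount within the spread (-1.38 ± 0.25 against -1.21 ± 0.06, n = 3, exact permutation p = 0.2). The difference went from -0.17 to -0.03 without castration + enzalutamide replicate 1.

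The combined group was compared in the same way with enzalutamide alone, which asks what absence of DHT adds. MKI67 was at 4.33 ± 1.51 against 6.75 ± 0.71 TPM (-0.57 ± 0.22, limma adjusted p = 0.412) and KLK3 at 14.2 ± 2.21 against 18.3 ± 1.92 TPM (-0.34 ± 0.11, adjusted p = 0.412), neither called. With quantile normalization KLK3 was at -0.20. G2/M and mitosis genes had a median of -0.43, with all 35 below 0, 0 called and 16 falling when adjusted over the list alone (camera adjusted p = 3.19e-09, and adjusted p = 0.82 with an estimated correlation). With a GC trend removed the median was -0.25, with 31 of 35 below 0. G1/S and DNA replication had a median of -0.29, with 0 called and 12 falling when adjusted over the list alone (camera adjusted p = 3.31e-07, and adjusted p = 0.82 with an estimated correlation). The median was -0.18 with median-of-ratios scaling. Homologous recombination (camera adjusted p = 0.00333, and adjusted p = 0.82 with an estimated correlation), androgen-activated (camera adjusted p = 0.0209, and adjusted p = 0.82 with an estimated correlation) and androgen-repressed genes (camera adjusted p = 0.0268, and adjusted p = 0.82 with an estimated correlation) also lay below other genes. The androgen-activated median of -0.21 was -0.07 without castration + enzalutamide replicate 1, -0.09 with median-of-ratios scaling and -0.12 with a GC trend removed. Mitochondrially encoded mRNAs (camera adjusted p = 2.80e-08, and adjusted p = 0.82 with an estimated correlation), the respiratory chain (camera adjusted p = 1.11e-05, and adjusted p = 0.82 with an estimated correlation) and immediate early genes (camera adjusted p = 0.0159, and adjusted p = 0.82 with an estimated correlation) lay above. Over 37 lists, camera called 8 in this comparison and fry called 0. Without castration + enzalutamide replicate 1 the mitochondrially encoded median went from 0.32 to 0.06, with 4 of 13 genes below 0. It was 0.54 without castration + enzalutamide replicate 3 and 0.53 with a GC trend removed, with 0 of 13 below 0. The androgen score was -1.38 ± 0.25 against -1.16 ± 0.02 (n = 3), with all 3 combined libraries below all 3 enzalutamide libraries (exact permutation p = 0.1, adjusted p = 0.15 over 6 comparisons). The difference went from -0.22 to -0.08 without castration + enzalutamide replicate 1. Again limma called only AL049650.2 (1.72 to 2.84 TPM with enzalutamide and 0.05 TPM or less in control, adjusted p = 0.00615). There were 1664 genes at an unadjusted p under 0.05, and other settings called 0 to 5.

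The interaction asked whether enzalutamide acted differently with and without DHT. Enzalutamide changed KLK3 by -4.97 with DHT and by 0.30 without it, a difference of 5.26 ± 0.15 (limma adjusted p = 1.05e-08). AOC1 changed by 4.12 with DHT and 0.32 without (difference -3.79 ± 0.18), MYC differed by 1.02 ± 0.20, HK2 by 1.09 ± 0.23 and AR by -1.41 ± 0.23 (adjusted p = 0.00134). DNM1L differed by 0.01 ± 0.22 (adjusted p = 0.983), not called, and by 0.20 without castration + enzalutamide replicate 1. Of the G2/M genes, 33 of 35 rose and 0 fell (34 and 0 adjusted over the list alone) in this difference, with a median of 1.38 (camera adjusted p = 8.47e-26, and adjusted p = 0.151 with an estimated correlation), and of the androgen-activated genes 15 of 29 rose and 2 fell (the same numbers as when adjusted over the list alone) (camera adjusted p = 1.21e-10, and adjusted p = 0.268 with an estimated correlation). MYC targets in ribosome biogenesis had 23 up and 1 down of 32 (23 and 2 adjusted over the list alone) (camera adjusted p = 3.41e-14, and adjusted p = 0.151 with an estimated correlation), the ATF4 list 12 up and 0 down of 22 (13 and 0 adjusted over the list alone) (camera adjusted p = 5.19e-09, and adjusted p = 0.151 with an estimated correlation), and autophagy and lysosome genes 2 up and 13 down of 24 (2 and 14 adjusted over the list alone) (camera adjusted p = 0.00668, and adjusted p = 0.643 with an estimated correlation). In all limma called 4965 genes, 1509 up and 3456 down. The share up was 30.4% on the TPM scale, where the median over all genes was -0.22, and 53.2% of 4964 with median-of-ratios scaling. Of the 4965, 4964 had a sign opposite to the castration response. Both contrasts use the control and castration libraries, and in 100 simulations of no change 89.3% of as many genes had opposite signs on average. The highest simulated share was 100%, so the tally of signs is no evidence of an interaction.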

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

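For castration + enzalutamide replicate 1, the tests of the mitochondrial share and of GC content were chosen only after results were seen, in place of a correlation test and a label-swap test that had pointed the same way, as were both tests of the smaller combined response, the simulation of signs and single values without that library.

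The effect of enzalutamide differed between media without and with DHT in 4965 genes. Among those with the largest differences, KLK2 changed by -5.01 with DHT and 0.32 without it (difference 5.33, adjusted p = 1.43e-06), KLK3 by -4.97 and 0.30 (5.26, adjusted p = 1.05e-08) and KLK4 by -2.77 and 0.33 (3.10, adjusted p = 1.74e-08). AOC1 changed by 4.12 with DHT and 0.32 without (-3.79, adjusted p = 6.15e-07) and PCDH11X by 2.69 and -0.86 (-3.55, adjusted p = 1.38e-04). Without castration + enzalutamide replicate 1 the -0.86 was -0.43. The values of PCDH11X are uncertain, since PCDH11Y is a near-identical copy. The short RNA genes MIR6850 (5.53), MIR4763 (5.12), MIR6506 (-3.95) and MIR1306 (-3.52) passed too, with uncertain TPM.

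The combined response was smaller than the sum of the single responses: its slope on the castration response was 0.944 over the genes called in castration, and 0.977 on the enzalutamide response over the genes called there. The values argue against a floor of low TPM as the cause: among 2605 genes called in castration, with the control, castration and enzalutamide means and the mean expected from additive effects all at 20 TPM or more, the slope was 0.898, where additive effects gave 1.94. The signs are no evidence of a smaller combined response. Of 4965 interactions 4964 were opposite to the castration response, but so were 89.3% on average, and up to 100%, in 100 simulations of no change. The slopes are those that would follow if either single treatment reached nearly the full response at 72 h, a hypothesis found and tested on the same data. Doses and times other than these would be needed to test it.

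Cell-cycle genes were lower with both treatments than with castration alone, with a median of -0.50 over the 35 G2/M genes. By library, the mean log2 value of these genes relative to control was -1.67, -1.57 and -2.07 in castration. It was -2.41, -2.27 and -2.13 in the combined group. Castration replicate 3 thus lay close to castration + enzalutamide replicate 3, and the size of the difference rests mostly on castration replicates 1 and 2. Without castration + enzalutamide replicate 1 the median was -0.45, and with median-of-ratios scaling it was -0.36, so neither that library alone nor a shift of all values by a single factor accounts for it. Among 10000 random lists matched on expression and transcript length the median lay at percentile 0 (their 2.5th percentile was -0.27), which argues against transcript length. A GC trend stays open as a part of it, since its removal left -0.29. An added effect of both treatments stays open too: 0 of the genes were called by limma over all genes (3094 of 15015 genes had an unadjusted p under 0.05) and 25 of 35 fell when adjusted over the list alone (camera adjusted p = 2.16e-10, and adjusted p = 0.716 with an estimated correlation). Over 37 lists, camera called 8 in this comparison and fry called 1.

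Castration + enzalutamide replicate 1 stood apart from its group, with a mitochondrial share of 24.1% and an androgen score of -1.67 against -1.27 and -1.21 in its groupmates, farther from the controls than they were. Its mean log2 value of androgen-repressed genes relative to control was 0.25, nearer to control than their 0.60 and 0.68. The median of all tested genes in this library lay 0.32 below the mean of the library medians. Its lower androgen score therefore cannot be read as a stronger androgen response. The values argue against a single factor from the larger mitochondrial share: with median-of-ratios scaling the root mean square deviation from groupmates was 0.481 (0.526 before), above the 0.387 of any library of the other groups. Castration + enzalutamide replicate 3 also lay above that bound, at 0.408 (0.446 before), so the bound does not set replicate 1 alone apart. The deviation of replicate 1 from groupmates correlated with GC content at rho = 0.373 (-0.414 for replicate 3), so GC content stays open as a part. Removal of a GC trend raised its lowest correlation with groupmates only from 0.966 to 0.969, below the 0.978 of the other groups, so GC content is not the whole cause. The 0.966 was with replicate 3, against 0.974 with replicate 2. The deviation of replicate 1 correlated with transcript length across genes at rho = -0.156, which lies between the bounds set, so unequal recovery by length cannot be told apart from other causes. The design gives no biological explanation within a group, and none was tested.

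Groups of 3 and 3 allow only 10 splits of 6 libraries, too few for a share under 0.05. For castration versus control the real split called 6268 genes, the most of any (1 of 10 as large), and the highest other called 1. For enzalutamide versus control these were 5797 (1 of 10) and 6. For the combined group versus control they were 5883 (1 of 10) and 1003, the latter from control replicate 1 together with castration + enzalutamide replicates 2 and 3, which shows some structure of the samples. Combined versus castration called 1 (2 of 10 splits as large, highest other 1), combined versus enzalutamide 1 (4 of 10, highest other 1) and enzalutamide versus castration 0 by limma (10 of 10, highest other 2; 566 at an unadjusted p under 0.05). For the interaction, 1 of 100 drawn splits, the real one, called as many as 4965, and the highest other called 4748. That split and those with 3403 and 3263 were the only others that kept the 3 controls together; splits that part the controls add the difference between control and treated libraries to the residuals, so their counts of 2 or fewer say nothing on an interaction. The count mainly follows control against treated, and these splits leave open whether chance plays a part.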

How the results depend on the processing

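Tests with the mitochondrial share as a covariate, with both libraries of the largest shares left out, with median-of-ratios scaling and combined-group library 1 left out, and with a GC trend removed were chosen only after results were seen. Of 481 named calls against control, 440 kept direction and call in every alternative and 41 lost the call in at least 1; of 19 without a call, 13 gained it in at least 1. CCND1 in the combined group versus control, not called in the main fit, reversed from -0.00 to 0.18 with the mitochondrial covariate and was called there. Calls against control stayed within 1.5 times under every alternative, over left-out libraries at 4947 to 7662 for castration, 4629 to 7195 for enzalutamide and 4854 to 6428 for the combination, and at 3688 to 6272 for the interaction. The replicate block gave 5603, 5156, 5307 and 3987; numbers showed no pairing, as 0 of 18 pairs of libraries with the same number correlated over 0.1 after removal of the group means. Counts between treated groups were small and moved. Combined versus castration (1) gave 2 with a pseudocount of 0.1 or 0.5, 5 with no filter or the GC trend removed, 0 with a filter of 5 TPM, 4 with median-of-ratios or upper-quartile scaling, with abundant and mitochondrial genes left out, with only the 2 groups or with the mitochondrial covariate, and 3 with quantile normalization, with both libraries left out or with median-of-ratios scaling and library 1 left out. Combined versus enzalutamide (1) gave 5 with no filter, 3 with both libraries left out, 2 with the block and median-of-ratios scaling, and 0 with a filter of 5 TPM, the block, the covariate, the GC trend removed or median-of-ratios scaling and library 1 left out. Enzalutamide versus castration (0 by limma, 566 at an unadjusted p under 0.05) gave 6 with no filter, 5 with the covariate, 2 with any of the 3 scalings or abundant genes left out, and 1 with either pseudocount, a filter of 5 TPM, both libraries left out or median-of-ratios scaling and library 1 left out. Leaving out single libraries gave 1 to 2284, 0 to 2 and 0 to 2; the cause was not tested. Androgen scores went to -1.31 and -1.27 with a pseudocount of 0.1 and -1.33 and -1.25 with median-of-ratios scaling for castration and enzalutamide, and to -1.27 to -1.14 and -1.22 to -1.09 over left-out libraries. The correlation of responses was 0.88 with a pseudocount of 0.1 and 0.913 to 0.937 over left-out libraries. Of 111 list tests against control, 48 lost the call with an estimated correlation. These were all the camera calls there, so 0 were left. Fry ended 2 of the calls and added 23. The read depth is unknown, so what it limits cannot be said.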

Other observations

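All values here were chosen only after results were seen. Families of genes that share a symbol stem were tested by camera over 72 families. Among genes of mitochondrial ribosomal proteins, more fell than rose with each treatment: in castration 31 of 49 MRPL genes fell and 2 rose, with a median log2 fold change of -0.35 (camera adjusted p = 3.73e-11, and adjusted p = 0.101 with an estimated correlation), and 22 of 29 MRPS genes fell and 0 rose by limma (median -0.38, camera adjusted p = 1.88e-08, and adjusted p = 0.101 with an estimated correlation). The inner-membrane import genes (TIMM) had 10 of 15 down and a median of -0.49 (camera adjusted p = 7.07e-06, and adjusted p = 0.101 with an estimated correlation). With enzalutamide, 28 of 49 MRPL genes fell and 2 rose (camera adjusted p = 1.15e-08, and adjusted p = 0.147 with an estimated correlation) and 23 of 29 MRPS genes fell (camera adjusted p = 8.62e-08, and adjusted p = 0.147 with an estimated correlation). In the combined group versus control, 29 of 49 MRPL genes fell and 1 rose (camera adjusted p = 4.96e-06, and adjusted p = 0.329 with an estimated correlation), 21 of 29 MRPS genes fell (camera adjusted p = 8.60e-06, and adjusted p = 0.293 with an estimated correlation) and 12 of 15 TIMM genes fell. Nuclear pore genes (NUP) went from 9 of 22 down in castration (camera adjusted p = 0.00114, and adjusted p = 0.931 with an estimated correlation) and 10 of 22 with enzalutamide to 16 of 22 in the combined group, a difference that was not tested. Over all 15015 genes, calls down also went from 2427 in castration and 2448 with enzalutamide to 3210 in the combined group. In castration, 14 of 35 VPS genes, which sort vesicles to the lysosome, rose and 0 fell (median 0.30, camera adjusted p = 0.0176, and adjusted p = 0.931 with an estimated correlation). With enzalutamide 13 rose and 0 fell (camera adjusted p = 0.0239, and adjusted p = 0.932 with an estimated correlation), and in the combined group 9 rose and 0 fell, without a camera call (adjusted p = 0.0771). Of the histone demethylase genes KDM, 12 of 18 rose and 1 fell in castration (median 0.36, camera adjusted p = 0.0439, and adjusted p = 0.931 with an estimated correlation). Camera called them neither with enzalutamide (8 up and 1 down, adjusted p = 0.0678) nor in the combined group (4 up and 2 down, adjusted p = 0.195).

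By gene type, 381 of 1838 lncRNA genes rose and 166 fell in castration, so that 69.7% of the lncRNA calls were up, against 60.3% for protein-coding genes. In the combined group 61.4% of lncRNA calls and 43.6% of protein-coding calls were up. Of 143 snoRNA genes, 13 fell and 0 rose by limma in castration, and 18 fell and 1 rose in the combined group. As poly(A) RNA was measured, snoRNA transcripts without a poly(A) tail are not covered. The nuclear lncRNA MALAT1 ranged from 770.01 to 1271 TPM in the controls, from 1919 to 2053 TPM in castration, from 1207 to 2003 TPM in enzalutamide and from 1666 to 3132 TPM in the combined group, highest in castration + enzalutamide replicate 1. Directions by type shift with the scaling, as those of all genes do.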
